A study of Gallus gallus with 4 samples.

How the data were processed

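The series holds 4 small RNA libraries of chicken monocyte-derived macrophages, grouped by the labels into infected and uninfected cells; the times of the infected cells (3 h and 36 h) come from the group labels and those of the uninfected cells from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq kit by a sequencing company. Bowtie and the genome build galGal4 are named in the submitters' processing notes, without a version. The tools used for counting, scaling and comparison, the trimming, and the treatment of reads that match several miRNAs are not given in the sources used here. Nothing in the labels says whether the cultures came from the same birds.

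The authors deposited 2 tables, 1 per time, each with 573 miRNA names, a value in the infected and in the control library, a log2 fold change, a p-value, a q-value and a call. The deposited values are a scaled signal, not counts: each column is a set of reads per mature miRNA multiplied by a factor of its own. The deposited log2 fold change is the log2 ratio of the scaled values where both are above 0, per the file headers and a check on the values. The deposited p-values and q-values compare 2 libraries, and the test behind them is not given in the sources used here. At 3 h 65 and at 36 h 67 names carry no values.

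In every column all values above 0 (251, 251, 226 and 240) were whole multiples of 1 step within 0.01 of a read, so reads were recovered by dividing by that step; the totals are 5351940, 4937253, 6052056 and 5402297. Values below 1 are listed as 0 in the deposited tables, so a listed 0 stands for at most 5 reads, or 6 in the 36 h control. Because the unit is not counts, no count model was run, and the rule fixed before the data were examined for that case was used: the ratio of reads per 1000000 miRNA reads (RPM), at least 2-fold, with at least 10 RPM in at least 1 of the 2 libraries. Where a miRNA was listed at 0 in 1 library, the largest number of reads a listed 0 can stand for was used to decide the call, and no fold is printed. The 95% intervals are exact conditional binomial (Clopper-Pearson) intervals from the recovered reads, and for the difference between times normal intervals of the log2 ratio; they were added after the data were seen, no call was made from them, and since PCR copies are not independent molecules they cover counting error only. All 19 calls at 3 h and all 22 at 36 h had intervals that exclude equal shares.

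Named miRNAs followed a rule fixed before the data were examined: per comparison the 12 highest and 12 lowest past the 2-fold rule, the 5 most abundant, members of fixed lists as examples, and the 5 largest differences between times in each direction. Opposite arms, miR-2954 and some further called miRNAs were named after their values were seen. The 19 lists of miRNAs (families, functions and markers of other cell types) were also fixed beforehand. A list takes every arm and copy of a listed miRNA, and a listed name without a letter also takes the lettered names, a reading chosen after the names were seen. For lists with at least 3 members the median log2 ratio was placed among 10000 random lists. For each member a random one was drawn on its own from the 20 miRNAs nearest to it in level. Both arms of a hairpin were thus not drawn together. This describes these libraries and is no test of conditions.

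Alternatives set beforehand were median-ratio scaling, totals without the 5 most abundant miRNAs, no filter and a filter of 50 RPM, thresholds of 1.5-fold and 4-fold, a pseudocount of 1 RPM, and for lists the more abundant arm of each miRNA; a further one, no demand on the counting interval, is the rule used and so tests nothing. Alternatives chosen after the data were seen were the deposited scale, totals without miR-21-5p, a counting interval that excludes equal shares, the 36 h control as reference for the 3 h infected library, and list names exactly as listed. Neighbouring miRNA genes (within 10 kb) were taken from a RefSeq gene table of GRCg7b, which is not the authors' build, so no coordinates are given; 136 of the 144 miRNAs compared at 3 h (94.4%) matched a gene in it. No miRNA sequences or reference genome were used here, so base composition was not examined.

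The procedure was tested on simulated reads drawn from the real shares and depths, with 20 miRNAs changed 3-fold and 20 changed 6-fold, up or down, outside the 5 most abundant. At 3 h, with 132 miRNAs that could be drawn, 19 of the 20 changed 3-fold and 20 of the 20 changed 6-fold were called; at 36 h, with 126, all 20 of each were called. No unchanged miRNA was called among 99 at 3 h and 93 at 36 h. Apart from the changed miRNAs, the simulated libraries differed by counting error alone, with no spread between cultures or from PCR. The result thus says nothing about false calls from such spread. Of 60 lists drawn without any change, 0% at 3 h and 5% at 36 h fell outside the central 95% of the random lists. These were random picks, unlike the paired arms in many of the fixed lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.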

Results

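Small RNAs were sequenced from primary chicken macrophages, grown from the blood monocytes of White Leghorn birds, after infection with J subgroup avian leukosis virus (ALV-J), a chicken retrovirus, and from uninfected macrophages of the same kind. The series held 4 libraries, 1 infected and 1 uninfected at each of 2 times, 3 h and 36 h. With 1 library per group no difference had a replicate check, and the comparisons below are between libraries, not conditions. The libraries held 5351940 (infected, 3 h), 4937253 (control, 3 h), 6052056 (infected, 36 h) and 5402297 (control, 36 h) miRNA reads. Values are shares in reads per 1000000 miRNA reads (RPM), miRNAs are named without the chicken prefix gga-, and a miRNA is called higher or lower when it was at least 2-fold apart and reached 10 RPM in at least 1 of the 2 libraries. Intervals are 95% counting intervals of the log2 ratio and cover counting error in these libraries only.

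miR-21-5p, one of the most abundant miRNAs of macrophages, made up 47.1% of the miRNA reads of the 3 h infected library, 50.4% of its control, 58.6% of the 36 h infected library and 47.4% of its control. miR-146b-5p, of a family that restrains Toll-like receptor signalling, took 13.4% and 8.76% at 3 h and 12.2% and 11.0% at 36 h, in the infected and the control library respectively. miR-148a-3p took 12.3% and 12.7% at 3 h, and 7.91% and 13.1% at 36 h. let-7f-5p stayed between 2.68% and 3.94% and let-7i between 1.94% and 2.78% in the 4 libraries. miR-223 and miR-142-3p, both typical of myeloid or other blood cells, were present at 727 to 976 and at 771 to 1590 RPM.

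The first comparison asked which miRNAs differed between infected and uninfected macrophages 3 h after infection. Of 144 miRNAs, 16 were higher and 3 lower in the infected library. miR-155, which rises when macrophages are activated and whose host transcript was first found at integration sites of avian leukosis virus, stood at 936 RPM against 76.0, which is 12.3-fold higher (log2 3.62, interval 3.47 to 3.78). miR-21-3p, the lesser arm of the miR-21 hairpin, was 7.53-fold higher (74.7 against 9.92 RPM), while the miR-21-5p arm had a log2 ratio of -0.10. Both arms of miR-222b were higher, the 5p arm 4.26-fold (285 against 67.0 RPM) and the 3p arm 3.12-fold (82.0 against 26.3). miR-31-5p was listed at 0 in the control library and at 11.4 RPM in the infected one.

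Further miRNAs that were higher at 3 h had mostly 1 arm of the hairpin apart. miR-32-5p stood at 669 against 229 RPM (log2 1.55), miR-30a-5p at 25014 against 12486 (interval of the log2 ratio 0.99 to 1.02), miR-30e-5p at 9197 against 4219 (2.18-fold), miR-29b-3p at 68.8 against 28.6 (log2 1.27) and miR-148a-5p at 105 against 43.7 (log2 1.27). The opposite arms miR-32-3p, miR-30a-3p, miR-30e-3p and miR-148a-3p had log2 ratios of -0.40, -0.06, -0.28 and -0.05. miR-142, a miRNA of blood cells, had both arms apart, miR-142-3p at 1590 against 771 RPM (log2 1.04) and miR-142-5p at 1493 against 744 (log2 1.01). Low-level members were miR-365-2-5p (log2 2.42), miR-33-5p (1.71), miR-17-3p (1.38) and miR-16-1-3p (1.02), none above 23.4 RPM in the infected library. Some calls lay close to the 2-fold line. Totals without miR-21-5p, chosen after the data were seen, shift the 3 h log2 ratios by -0.09. That puts miR-30a-5p, miR-16-1-3p and both arms of miR-142 under 2-fold.

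The 3 miRNAs that were lower at 3 h included markers of other cell types. miR-122-5p, the main miRNA of liver, stood at 1.68 RPM against 53.9, which is 32.0-fold lower (interval of the log2 ratio -6.15 to -4.06). miR-451, a miRNA of red blood cells, stood at 10.8 against 34.0 RPM (log2 -1.65). miR-128-1-5p, whose hairpin is best known from neural tissue, stood at 14.9 against 37.3 (log2 -1.32), while its abundant arm miR-128-3p had a log2 ratio of -0.34.

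Several of these calls depended on the control library used. miR-30a-5p stood at 12486 RPM there, against 23012 in the 36 h control and 15755 in the 36 h infected library, and miR-32-5p at 229 against 539 and 387. With the 36 h control in place of the 3 h control, an alternative chosen after the data were seen, 11 miRNAs were higher than control, 7 of them among the 16. These 7 were miR-155, miR-21-3p, both arms of miR-222b, miR-31-5p, miR-33-5p and miR-365-2-5p. Against the 36 h control miR-21-3p was 2.18-fold higher (74.7 against 34.2 RPM) and miR-33-5p 2.17-fold, while miR-155 was 12.7-fold higher; the log2 ratio of miR-30a-5p was then 0.12 and that of miR-142-3p 0.40. miR-451, lower against the 3 h control, was higher against the 36 h control (10.8 against 2.96 RPM, log2 1.87). miR-122-5p was at 1.68 against 8.14 RPM there (log2 -2.28), under the 10 RPM needed for a call. The median log2 ratio of all compared miRNAs at 3 h was -0.16; on the scale of the deposited values, which adds 0.16 to each ratio, 17 miRNAs were higher, with miR-147 added (log2 1.14 in place of 0.98), and 3 lower.

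**Figure D1:**
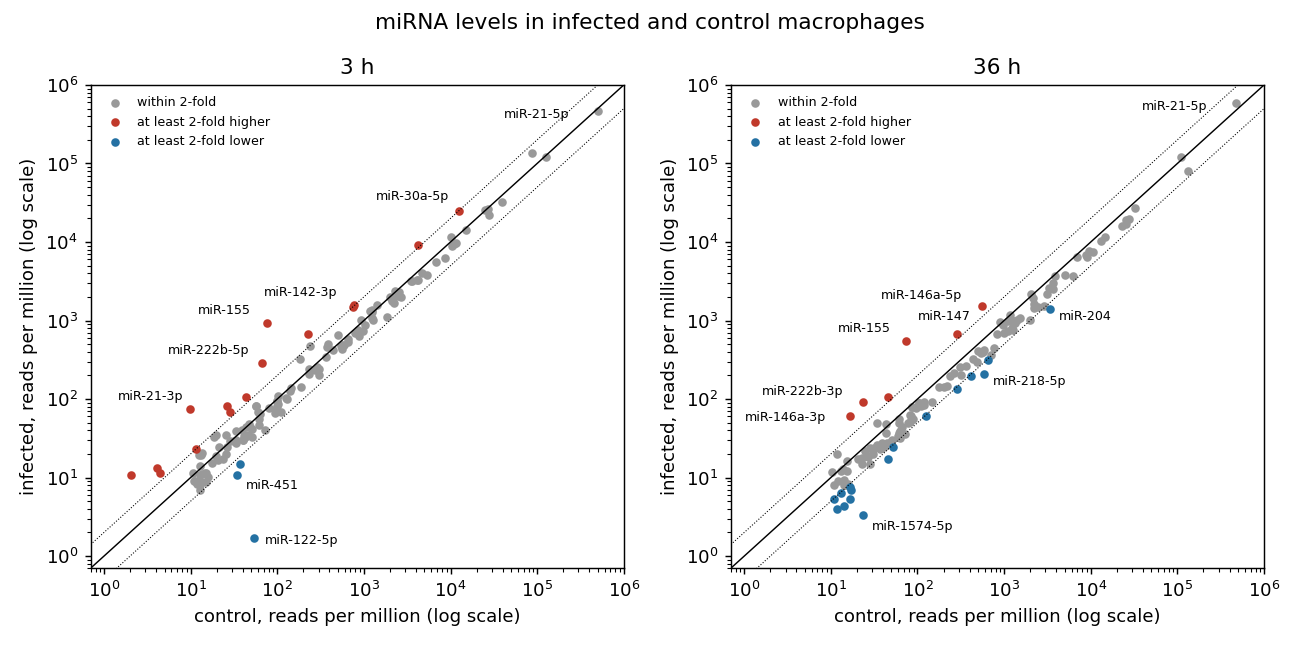
Reads RPM of each compared miRNA in the control library (x axis, log scale) against the infected library (y axis, log scale) at 3 h (left) and 36 h (right); each point is a miRNA listed above 0 in both libraries, the solid line marks equal values and the dotted lines 2-fold. miR-155 stands at 936 against 76.0 RPM at 3 h and at 550 against 73.9 at 36 h, and at 36 h most points lie below the line of equal values.

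The second comparison asked the same at 36 h. Of 136 miRNAs, 6 were higher and 16 lower in the infected library. miR-155 was 7.45-fold higher (550 against 73.9 RPM; log2 2.90, interval 2.75 to 3.05). miR-146a, induced by NF-kB and known to act back on Toll-like receptor signalling, had both arms higher, miR-146a-5p 2.75-fold (1524 against 554 RPM) and miR-146a-3p 3.72-fold (61.3 against 16.5). Both arms of miR-222b were again higher, the 3p arm 3.86-fold and the 5p arm 2.36-fold, and so was miR-147, known to be induced in stimulated macrophages, at 665 against 287 RPM (2.32-fold). How reads shared between near-identical family members, such as miR-146a and miR-146b, were assigned is not given in the sources used here.

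Among the 16 lower miRNAs, miR-1574-5p stood at 3.30 against 23.5 RPM (log2 -2.83, interval -3.59 to -2.14), and its 3p arm at 5.29 against 16.7 (log2 -1.66). miR-218-5p stood at 206 against 581 RPM (log2 -1.50), miR-204 at 1393 against 3357 (log2 -1.27) and miR-1416-5p at 17.0 against 45.4 (log2 -1.41). miR-126-5p, miR-1747-5p, miR-125b-3p and miR-2131-5p had log2 ratios of -1.73, -1.58, -1.31 and -1.07. The median log2 ratio of all compared miRNAs was -0.49 at 36 h, and only 11.0% of them were above 0. The deposited scale adds 0.45 to each ratio, and on it 7 miRNAs were higher and 5 lower, so that 58.3% of the calls were higher in place of 27.3%. The 5 were miR-1574-5p, miR-126-5p, miR-1574-3p, miR-1747-5p and miR-218-5p; miR-204 had a log2 ratio of -0.82 on that scale. The 6 higher miRNAs were at least 2-fold higher on both scales, which the positive shift makes certain.

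The lists of miRNAs fixed before the data were examined were set against 10000 random lists matched on level. Random members were drawn one by one, while many lists hold both arms of a hairpin. Where such arms move together, as at 36 h and for miR-222b and miR-142 at 3 h, the random range may be too narrow. The inflammatory response list held 16 measured members, among them miR-222a and both arms of miR-222b, which entered because the listed name miR-222 was read, after the names were seen, as covering lettered names. At 3 h 4 of them were higher and none lower (miR-155, miR-21-3p and both arms of miR-222b), with a median log2 ratio of 0.19 at percentile 99.7. At 36 h 6 were higher and none lower (miR-155, both arms of miR-146a, both arms of miR-222b and miR-147), with a median of 0.23 at percentile 100. With names exactly as listed, 13 members were left, of which 2 were higher at 3 h (median 0.15, percentile 98.1) and 4 at 36 h (median 0.15, percentile 100), and none lower. Other members lay below 0 on the total scale, such as miR-221-3p (-0.20 at 3 h and -0.48 at 36 h) and miR-222a (-0.15 and -0.60). Of the 14 members of the myeloid list, 4 were also on the inflammatory list. At 3 h 3 of the 14 were higher, miR-21-3p and, close to the 2-fold line, both arms of miR-142 (median 0.09, percentile 98.1). At 36 h 2 were lower, both arms of miR-126 (median -0.29, percentile 95.9).

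At 36 h the 4 members of the miR-181 family, which were also the measured members of the lymphoid marker list, had a median log2 ratio of -1.08 at percentile 1.04, with 3 of them lower: miR-181b-5p at 195 against 416 RPM, miR-181a-3p at 135 against 286 and miR-181b-1-3p at 7.60 against 16.8. The stromal and endothelial marker list had a median of -1.05 at percentile 1.28, with miR-199-5p at 315 against 659 RPM and miR-126-3p at 60.5 against 124 among its 3 lower members. On the deposited scale these medians were -0.63 and -0.60, and none of these 6 miRNAs except miR-126-5p was 2-fold lower there. Both lists hold paired arms of the same hairpins, so their percentiles at 36 h may be too extreme. At 3 h both lists were nearer the other miRNAs, at percentiles 9.53 and 79.5.

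The other lists did not stand apart at either time, apart from the liver and neural markers at 3 h (3 members, median -1.32, percentile 0.32). The let-7 family had 10 members, none called, and percentiles of 5.01 at 3 h and 43.9 at 36 h. The percentiles at 3 h and 36 h were 64.2 and 70.6 for the miR-17 cluster and its paralogues, 80.1 and 37.8 for the miR-15 and miR-16 family, 73.7 and 48.0 for the miR-30 family, 35.2 and 15.1 for the miR-10, miR-99, miR-100 and miR-125 families, 59.5 and 32.3 for miRNAs tied to ALV-J in earlier work, and 25.1 and 76.6 for chicken miRNAs with 4-digit numbers. Lists with fewer than 3 measured members were given no percentile. miR-34a-5p, the measured member of the miR-34 family, stood at 501 against 389 RPM at 3 h and at 362 against 697 at 36 h. The muscle miRNA miR-1a-3p stood at 143 against 189 and at 141 against 178 RPM, and miR-451, the erythroid marker, was at 1.98 and 2.96 RPM at 36 h. No miRNA of the epithelial or the embryonic list reached 10 RPM.

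**Figure D2:**
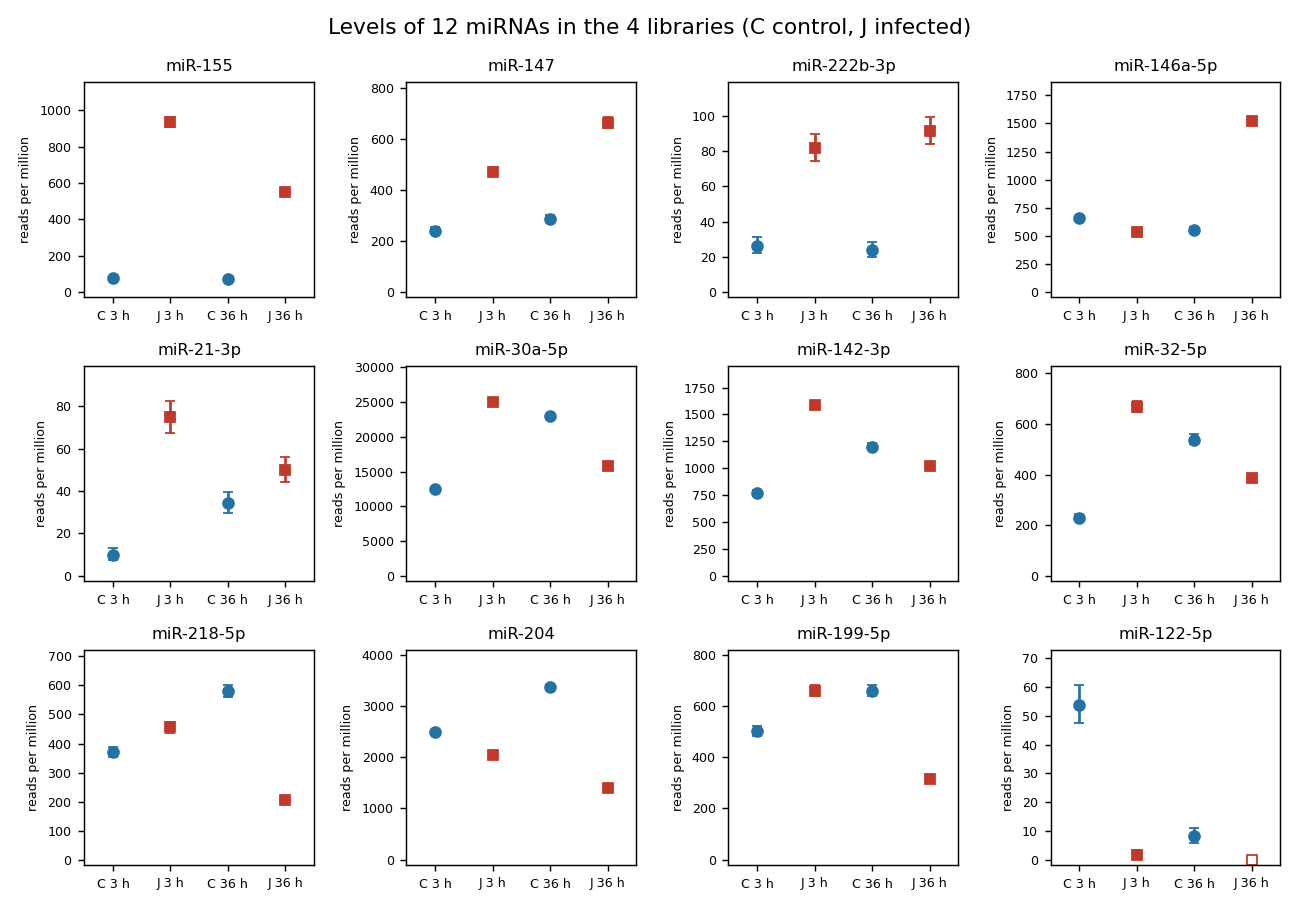
Reads RPM (y axes, linear, 0 included) of 12 miRNAs in each library, with control libraries as blue circles (C) and infected libraries as red squares (J); bars are 95% Poisson intervals of the reads, often smaller than the symbol, and an open symbol marks a miRNA listed at 0. miR-155 and miR-222b-3p are at least 2-fold higher in both infected libraries, and miR-147 and miR-146a-5p in the 36 h infected library. miR-147 is just under 2-fold at 3 h (log2 0.98), and miR-30a-5p is lowest in the 3 h control at 12486 RPM.

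The third comparison set the infection ratios of the 2 times against each other. Among 142 miRNAs the ratio at 36 h exceeded that at 3 h by at least 2-fold for 4 and fell short of it by at least 2-fold for 24, with a median difference of -0.37. miR-146a-5p had the largest positive difference (1.76 on the log2 scale, interval 1.66 to 1.85), from 534 against 656 RPM at 3 h to 1524 against 554 at 36 h. It was followed by miR-1649-5p (1.18), miR-146a-3p (1.10), miR-451 (1.07, interval -0.09 to 2.23) and miR-128-1-5p (0.70). The lowest differences were those of miR-1574-5p (-3.38), miR-21-3p (-2.37), miR-148a-5p (-2.23), miR-32-5p (-2.02) and miR-33-5p (-1.92). Of the miRNAs compared at both times, 12 were higher at 3 h and 6 at 36 h. The 3 that were higher at both were miR-155 and both arms of miR-222b, where independent lists would share 0.53. The arms of miR-222b share a hairpin and are not independent draws, so the 3 are not separate cases. Among the miRNAs compared at both times, 1 was lower at 3 h and 16 at 36 h. None was lower at both, where independent lists would share 0.12. Across the 142 miRNAs, which are not independent replicates, the ratios of the 2 times had a Pearson correlation of 0.45 and a Spearman correlation of 0.16, and without the 2 miRNAs farthest from the median at 3 h the Pearson correlation was 0.30. The times share no library. On the deposited scale 15 in place of 24 differences were below the 2-fold line.

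**Figure D3:**
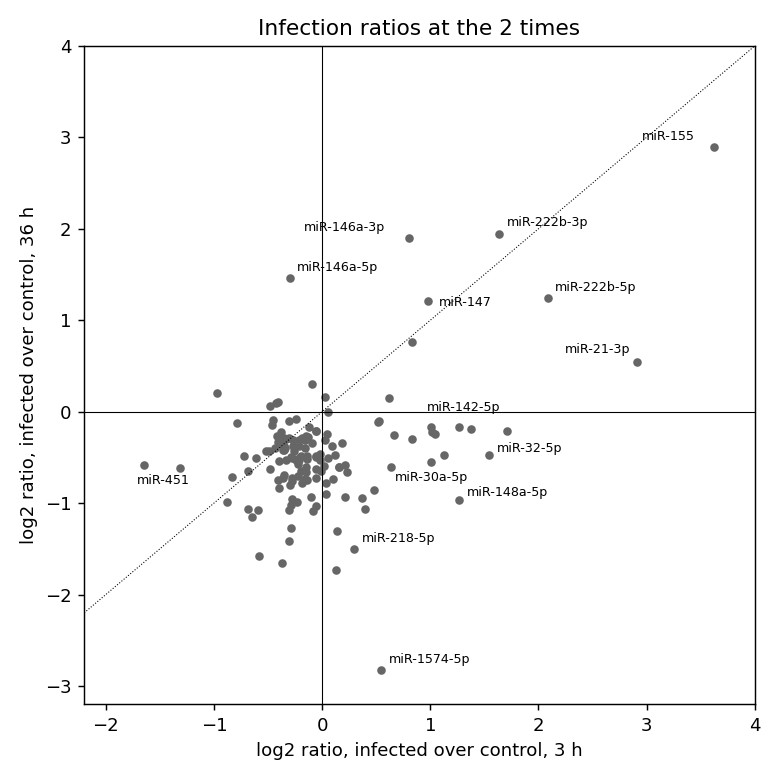
Log2 ratio of infected over control at 3 h (x axis) against 36 h (y axis). The points are the 142 miRNAs listed above 0 in all 4 libraries, with at least 10 RPM in at least 1 of them. Lines mark 0 on each axis and the dotted line equal ratios. miR-155 lies far to the upper right (3.62 and 2.90), miR-146a-5p is above 0 at 36 h only (-0.30 and 1.46), and miR-21-3p lies well below the line of equal ratios (2.91 and 0.54).

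The control libraries were set side by side as shares of each library, since the tables of the 2 times were scaled separately. Of 141 miRNAs, 5 were at least 2-fold higher at 36 h than at 3 h and 2 lower. The higher ones were miR-21-3p (34.2 against 9.92 RPM), miR-32-5p (539 against 229), miR-29b-3p (61.8 against 28.6), miR-16-1-3p (2.16-fold) and miR-30e-5p (9009 against 4219). The lower ones were miR-451 (2.96 against 34.0 RPM) and miR-122-5p (8.14 against 53.9). All 7 were also called in the same direction in the infected library at 3 h, a comparison that uses the same 3 h control library. miR-155 stood at 76.0 and 73.9 RPM in the 2 control libraries.

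The authors' deposited tables call 15 miRNAs at 3 h, 13 higher and 2 lower, and 8 at 36 h, 6 higher and 2 lower. In the authors' deposited tables every call has a log2 fold change beyond 1 and a q-value below 0.01, and no other miRNA meets both. In the authors' deposited tables the log2 fold change of miR-155 is 3.78 at 3 h and 3.35 at 36 h, and that of miR-146a-5p is 1.91 at 36 h. Of the calls, 14 at 3 h and 8 at 36 h were also at least 2-fold apart in RPM, the exception being miR-147 at 3 h. The p-values of the authors' deposited tables rest on 1 library per group. They were matched, to a median difference of 3.8e-06 at 3 h and 6.6e-05 at 36 h on the log10 scale, by a normal approximation that takes the ratio of the column totals as no change; taking equal scaled values as no change left differences of 0.18 and 0.50. On that reading the fold changes and p-values of the authors' deposited table of 36 h are centred 0.45 apart on the log2 scale.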

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

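The tests on the 3 h control library and on opposite arms were chosen after the results were seen, and the rule for neighbouring genes, set before as a median over all neighbours, was changed afterwards to a median per member. 8 miRNAs were at least 2-fold apart in RPM at 1 time and lay on the opposite side at the other on both scales. Both counting intervals, taken in RPM only, excluded equal shares. Median-ratio scaling adds 0.49 to the 36 h ratios, and those of miR-30e-5p and miR-32-5p were -0.48 each. With that scaling these miRNAs were thus no longer below control at 36 h. With 1 library per group the difference between times was not tested. miR-146a-5p lay below control at 3 h by less than 2-fold (log2 -0.30, with 0.80 for its 3p arm). At 36 h it was higher (log2 1.46), a difference of 1.76 on the log2 scale. The other 7 were above control at 3 h and below it at 36 h: miR-1574-5p (difference -3.38), miR-148a-5p (-2.23), miR-32-5p (-2.02), miR-218-5p (-1.80), miR-30e-5p (-1.60), miR-30a-5p (-1.55) and miR-199-5p (-1.46). On the deposited scale the 36 h ratios of miR-30a-5p, miR-30e-5p and miR-32-5p were -0.09, -0.02 and -0.02, so on that scale they were hardly apart at 36 h.

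Several of these belong to a wider pattern of 12 miRNAs that were higher at 3 h but, at 36 h, had a log2 ratio below 0.5 or were listed at 0. A change of whole hairpins is not decided for the members as a set. The opposite arms of the 10 members with a measured one had a median log2 ratio of -0.18, with 8 of them at -0.0522 or below. Both arms of miR-142 were higher, and each is counted here as the opposite of the other. The opposite arms of miR-16-1-3p and miR-365-2-5p are named without a copy number, so they may come from other copies. A change of shared primary transcripts is not decided either. The 10 neighbours of 4 members had a median of -0.0631. By member the medians were 0.52 for miR-29b-3p, -0.0065 for miR-16-1-3p, -0.12 for miR-17-3p and -0.43 for miR-30e-5p. The neighbours of miR-29b-3p were miR-29a-3p and miR-29c-3p. In the infected libraries these had 436 reads each at 3 h, and 483 and 484 at 36 h. They may be the same reads under both names, and so 1 measurement. A 3 h control library that stands apart may account for part of the pattern. For 6 of the 10 members listed above 0 in all libraries, it lay farther from the 36 h libraries than the 3 h infected library. These include miR-30a-5p, miR-30e-5p and miR-32-5p, and 6 of 10 is too near an even split to decide. Over 119 miRNAs with at least 10 RPM in every library, each library was set against the median of the others. Each library was then centred on its own median deviation, so a shift shared by most miRNAs is not counted. The log2 deviations had a standard deviation of 0.51 in the 3 h control and 0.45 in the 36 h control. In the infected libraries it was 0.52 at 3 h and 0.57 at 36 h. At least 2-fold away after centring were 8 miRNAs in the 3 h control and 4 to 6 elsewhere, so on that scale it hardly stood apart over all miRNAs. A loss of some sequences during extraction or ligation, and an early effect of the virus on single arms, were not tested.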

How the results depend on the processing

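With 1 library per group no replicate could be left out. The labels give no replicate numbers, and a fit over both times with time as a block, which takes the times as replicates, was not run. The planned test with an assumed biological spread was not run, since the deposited values are not counts. Of the settings below, the deposited scale, totals without miR-21-5p and the 36 h control as reference at 3 h were chosen after the data were seen. At 36 h the 16 lower miRNAs became 5 on the deposited scale, with median-ratio scaling and without the 5 most abundant, and 6 without miR-21-5p, which follows from the positive shift these scalings add; the 24 lower differences between times became 15, 14 and 10 under the first 3 of these. Without a filter, which admits more miRNAs, the lower counts were 15 at 3 h, 40 at 36 h and 41 for the difference, and the control libraries gave 11 higher and 10 lower. At 50 RPM, which admits fewer, 1 was lower at 3 h, 7 at 36 h, 3 higher and 1 lower between the controls, and 2 differences higher and 13 lower. At 1.5-fold 12 were lower at 3 h, 52 at 36 h, 14 higher and 7 lower between the controls, and 50 differences lower. At 4-fold 5 were higher and 1 lower at 3 h, 1 higher and 1 lower at 36 h, 0 higher between the controls, and 0 differences higher and 4 lower. All other counts of called miRNAs under the settings tried stayed within 1.5 times of the reported ones. No called miRNA among those named changed sign under the scalings and pseudocount tried. For ratios of 2 libraries this was fixed beforehand and is no sign of stability. The largest shift was 0.49, too small to reverse a 2-fold ratio, and a pseudocount added to both libraries keeps the sign. With the 36 h control as reference at 3 h, miR-451 turned from lower to higher (log2 1.87), since it was scarce in that control. Values of single miRNAs were counted under the alternatives other than totals without miR-21-5p. There 37 values of called miRNAs were under 2-fold, 8 of them with the 36 h control as reference. Most others were of lower miRNAs at 36 h by scaling. Another 6 values became 2-fold, of miR-147 and miR-146a-3p at 3 h, miR-21-3p at 36 h and the difference of miR-128-1-5p. Of the list medians under the alternatives, 151 moved by less than the half-width of the random range and 24 by more, mostly upward at 36 h by scaling; that of the inflammatory list at 36 h was 0.68 on the deposited scale. miRNAs under about 10 RPM rest on few reads, and a listed 0 hides up to 5 or 6.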

Other observations

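The tests in this part were chosen after the results were seen, except those on other differences between cultures and on levels per cell. The arms of a hairpin moved together at 36 h and hardly so at 3 h. Over the 27 hairpins with both arms compared at 36 h, the Spearman correlation of the log2 ratios of the abundant and the lesser arm was 0.78 and the median absolute difference 0.22, against 0.50 when arms were shuffled. Over the 30 hairpins at 3 h the correlation was 0.01 and the median absolute difference 0.44, against 0.51 when shuffled. At 3 h 8 hairpins had arms at least 2-fold apart in ratio (miR-21, miR-17, miR-148a, miR-146a, miR-30a, miR-30e, miR-32 and miR-33) and at 36 h 2 (miR-1574 and miR-1729). Hairpins are not independent replicates, and these values describe the 4 libraries.

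miR-2954, a Z-linked miRNA known to be more abundant in male birds, stood at 1123 and 1081 RPM in the infected and at 1858 and 1510 in the control libraries of 3 h and 36 h; its log2 ratio was -0.73 at 3 h and -0.48 at 36 h in RPM, and -0.57 and -0.03 on the deposited scale. The sex of the birds is not given in the sources used here. The 86 predicted miRNAs took at most 0.0071% of the reads of any library, and 1 of them reached 10 RPM at each time.

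miR-155 and both arms of miR-222b were at least 2-fold higher in the infected library at both times; miR-147, miR-146a-3p, miR-21-3p, miR-1729-3p and miR-146b-5p also lay above equal shares at both times, with intervals that exclude them, but were under 2-fold at 1 time or both and were not weighed. For the 3, the lowest log2 ratio over both times and all scalings was 1.24. This does not weigh library scaling, since the 3 were picked as at least 2-fold higher at both times. The lowest shift of any scaling tried was -0.09, so none could bring a 2-fold higher ratio to equal shares, whichever miRNAs were picked. Counting error alone is argued against for the 3, since the lowest lower bound of their intervals was 1.02. The 3 were picked by the 2-fold rule, and all 19 calls at 3 h and all 22 at 36 h excluded equal shares. The intervals thus add little to the calls themselves. A difference between the cultures other than the virus, such as the birds or the handling, cannot be told apart from infection with 1 library per group.

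At 36 h most miRNAs were lower in the infected library on the total scale, with a median log2 ratio of -0.49. A larger share of miR-21-5p in that library may account for much of this: with miR-21-5p left out of both totals the median was -0.14, which keeps 28.6% of its size. Whether the other miRNAs were also fewer per cell cannot be told apart from this, since the median of -0.49 has no spike-in or cell number to be scaled by. At 3 h miR-21-5p took a smaller share in the infected library, so its share does not produce the median of -0.16 there.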
